A study of Mus musculus with 8 samples.

How the data were processed

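The study sorted myeloid cells from mouse brain tumors into 8 libraries, 3 of microglia and 5 of bone marrow-derived macrophages (BMDM, monocyte-derived cells that enter the tumor from the blood). Tumors were GL261, a mouse glioma line, grown in the brain. Per the labels' protocols, the sort took cells positive for F4/80 and CD11b and negative for Ly6G. Microglia were CD45 low and CD49d low or negative, and BMDM were CD45 positive and CD49d high, with Ly6C low or negative in both. RNA was made into QuantSeq 3′ FWD libraries, which count the 3′ end of polyadenylated transcripts on one strand, and sequenced on a NextSeq500 as single reads. The labels do not say whether the libraries came from separate mice, so p-values measure the spread between these libraries.

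The authors deposited 1 table of raw read counts per gene, with whole numbers that sum to a different total in each library. The submitters' processing notes name FastQC, cutadapt, STAR, featureCounts, DESeq2 and the mm10 build, without versions or settings. Whether counting used strand, and how reads that match several places were treated, is not given in the sources used here. Counts of overlapping genes and of near-identical gene families (such as Ly6, Clec4, class I and class II histocompatibility genes, hemoglobins) are therefore less certain than others. The same holds for any gene with near-identical copies or pseudogenes. No gene, those of glycolysis included, was checked for reads shared in this way. The table held 55450 genes, of which 31187 had a count in at least 1 library. All identifiers (100%) and all names (100%) were found in the GENCODE M21 annotation of GRCm38 (mm10), from which positions and exon lengths were taken.

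The counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr (minimum count 10, minimum total count 15), which left 16467 genes. Libraries were scaled with TMM factors, and dispersions and quasi-likelihood fits were robust. The comparison was BMDM minus microglia over all 8 libraries, with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes carry standard errors derived from the F statistic, and CPM values are TMM-scaled and given with their SD. Log2 CPM values used a prior count of 2.

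Gene lists were fixed before the data were examined: 33 lists of pathways, cell states and other cell types. Each was tested with limma 3.58.1 camera on voom values with a preset inter-gene correlation of 0.01, adjusted over the 33 lists, and again with an estimated correlation and with fry. The rule for named genes was fixed at the same time. It took the 15 largest rises and 15 largest falls among called genes with a mean of at least 20 CPM and no overlap between groups, up to 3 called members per list and direction, and a set of sort, microglia, glucose, stress and immune genes named in advance. Gene models without a name, pseudogenes, ribosomal protein genes, antigen receptor segments, sort markers and hemoglobins were left out of its first part.

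Library totals ran from 5890406 to 16659154 counts. No pair of libraries within a group was alike within sampling noise, the lowest chi-square per degree of freedom being 21.1 (BMDM 1 and BMDM 2). The scripts were tested on simulated counts with 200 changed genes drawn from the real means, library sizes and spreads. With 5 BMDM against 3 microglia and 14808 simulated genes, 22.0% of genes changed by a log2 fold of 2, 50.0% of those changed by 3 and 70.0% of those changed by 4 were recovered, with 3 false calls among 74. A log2 fold of 1 was recovered for 2.0%, so a gene without a call here can still have changed by that much.

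Alternatives were DESeq2 1.42.0, RLE factors, library totals alone, no filter, a stricter filter (10 CPM in 3 libraries), limma-voom with and without sample quality weights, a replicate block, the BMDM replicates 1 to 3 alone, a test against a log2 fold of 1, and each library left out. Leaving out Gm42418, a gene model that overlaps ribosomal RNA, and the mitochondrial rRNA genes was added after seeing the data.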

Results

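Gene expression was measured by 3′ RNA sequencing in 2 populations of tumor myeloid cells, resident microglia (3 libraries) and BMDM (5 libraries), sorted from GL261 tumors in the mouse brain. Microglia libraries held 16659154, 10491469 and 11390715 counts, and BMDM libraries 1 to 5 held 5890406, 7063147, 7478255, 7510124 and 9169531. Gm42418 took 34.0% to 47.0% of the counts in microglia, 14.8% to 19.8% in BMDM 1 to 3, and 41.2% and 48.9% in BMDM 4 and BMDM 5. With Gm42418 and mitochondrial rRNA left out and each library thinned to 4151079 counts, 19721 to 21632 genes were detected in BMDM 1 to 3, against 13343 in BMDM 4 and 14536 in BMDM 5. Microglia 1, 2 and 3 gave 21916, 20543 and 17336 genes at that depth.

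**Figure D1:**
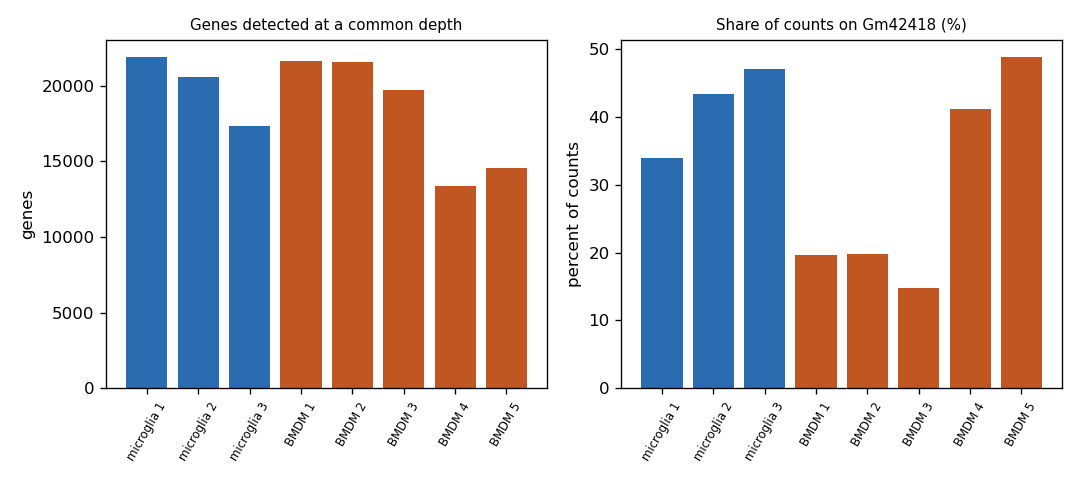
Genes detected in each library at a common depth of 4151079 counts (left) and share of counts on Gm42418 (right), with microglia in blue and BMDM in orange. BMDM 4 and BMDM 5 had the fewest genes, 13343 and 14536.

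The 2 populations were compared at the mRNA level in a study of immune suppression by macrophages in such tumors. BMDM had 29.8-fold more Ccr2 mRNA, the receptor that draws monocytes to CCL2, and 27.6-fold more Il10, an immunosuppressive cytokine (log2 fold change 4.79, or 6.32 without microglia 2, and not called without microglia 1 or microglia 3 or with limma-voom). Microglia had 14.9-fold more Sall1, a microglial transcription factor, and 24.1-fold more Csf1, a growth factor of macrophages. Of 16467 genes tested, 183 were higher and 134 lower in BMDM by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and each of these 317 had an absolute log2 fold change of at least 1. The libraries of the groups did not overlap for 307 of the 317 and for 12.98% of all genes tested, where chance gives 3.57%. With only BMDM 1 to 3 against microglia 1 to 3, 1028 genes were higher and 1312 lower, and all 317 were called again with the same sign. In that fit the groups also differed in their share of Gm42418, without overlap, so its added calls cannot be put down to cell type alone. Leaving out 1 library gave between 104 (without microglia 3) and 1138 (without BMDM 5) called genes.

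The sort separated the cells by CD49d, encoded by Itga4 (chromosome 2, 79255426 to 79333123, GRCm38), so a difference in this gene is set by the gate. Itga4 reached 76.1 ± 21.6 CPM (SD, n = 5) in BMDM and 12.1 ± 5.22 (n = 3) in microglia, with a log2 fold change of 2.66 (SE 0.43, adjusted p = 0.00451). Ly6c2 was higher in BMDM by 5.70 (SE 0.87, adjusted p = 0.00356), or 6.81 without microglia 1, although both gates took cells low or negative for Ly6C. Ly6c2 and Ly6c1 are near-identical, and Ly6c1 did not pass the test (log2 fold change -1.51, SE 1.47, adjusted p = 0.766). Over the settings Ly6c1 ran from -3.06 to -0.77, the latter with only BMDM 1 to 3. BMDM 3 held 5.83 CPM of it, against 0 to 1.60 in the other BMDM libraries. The gates also differed in CD45, low in microglia and positive in BMDM. Ptprc, which encodes CD45, had a log2 fold change of 0.52 (SE 0.38, adjusted p = 0.638) and was not called. Values for Itgam and Adgre1, the genes of CD11b and F4/80, were -0.11 (SE 0.56, adjusted p = 0.97) and 0.04 (SE 0.36, adjusted p = 0.985), with Itgam at -0.92 without BMDM 5. Ly6g had 1 count in each of 2 BMDM libraries and 0 in the other libraries, too few for a fold.

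The resident signature was higher in microglia. Of 30 measured genes of the microglia list, 13 were lower in BMDM and 0 higher (26 lower when adjusted over the list alone), with a median log2 fold change of -2.25. Camera gave an adjusted p of 7.3e-22, and adjusted p = 0.11 with an estimated correlation. Sall1 (chromosome 8, 89027235 to 89044162) fell by 3.90 (SE 0.46, adjusted p = 0.000748), from 70.1 ± 25.6 CPM (n = 3) in microglia to 4.67 ± 2.13 (n = 5) in BMDM. Siglech, a sialic acid-binding lectin, was at -3.95 (SE 0.48, adjusted p = 0.000817), and Sparc, a matrix glycoprotein, at -3.72 (SE 0.46, adjusted p = 0.000817). P2ry12, a purinergic receptor, and Slc2a5, a fructose transporter, were at -3.71 (SE 0.82, adjusted p = 0.0315) and -4.22 (SE 0.93, adjusted p = 0.0307). Both calls were lost without any 1 of the 3 microglia libraries or without BMDM 1 or BMDM 2, with adjusted p up to 0.30 for P2ry12, and Slc2a5 was at -5.75 without BMDM 3. P2ry12 was at -3.02 with only BMDM 1 to 3. Tmem119, another microglial marker, was at -1.35 (SE 0.55, adjusted p = 0.269), with 108 ± 75.6 CPM (n = 5) in BMDM and 275 ± 129 (n = 3) in microglia. Outside the list, Csf1 (chromosome 3, 107741048 to 107760469) fell by 4.59 (SE 0.42, adjusted p = 0.000148) and Adgrg1, an adhesion receptor, by 4.57 (SE 0.44, adjusted p = 0.000148). Nav3, a member of the list, and Plxdc2, Rapgef5 and Lrrc3, outside it, were also among the largest falls, between -3.65 and -3.95, with Plxdc2 at -3.34 without microglia 3 and Rapgef5 at -4.23 with only BMDM 1 to 3.

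BMDM carried the monocyte-derived signature, in which 23 of 38 measured genes were higher and 0 lower (31 higher when adjusted over the list alone). The median log2 fold change was 2.79, with a camera adjusted p of 2.6e-36, and adjusted p = 0.014 with an estimated correlation. It was the only 1 of the 33 lists past the threshold in that form of the test, and with only BMDM 1 to 3 none passed (adjusted p = 0.35 with an estimated correlation for this list, in which 29 genes were then higher). Ccr2 (chromosome 9, 124101950 to 124113557) rose by 4.90 (SE 0.47, adjusted p = 0.000148), from 4.15 ± 1.24 CPM (n = 3) to 125 ± 43.7 (n = 5). F10, coagulation factor X, rose by 5.55 (SE 0.64, adjusted p = 0.00068), and Tmem51 by 4.95 (SE 0.48, adjusted p = 0.000148). Chil3, a chitinase-like protein of alternatively activated macrophages, rose by 6.53 (SE 1.15, adjusted p = 0.00909), with 12 counts in the microglia libraries together, all of them in microglia 2. With all libraries this was 92.5-fold. Against microglia 1 and 3 alone, picked because they had 0, counting error gave a lower limit of 331-fold (3 counts over both libraries). Microglia 3 lacked 2.76% of genes expected at 20 or more counts, so transcripts lost from a library are not covered by that limit. The call of Chil3 was lost without microglia 3, with an adjusted p of 0.092. Mefv, Inhba, Napsa, Ecm1 and the C-type lectins Clec4d and Clec4e were among the other large rises, between 4.38 and 5.42. Without microglia 2, Ecm1 was at 4.97 and Clec4e at 5.80, and with only BMDM 1 to 3 Mefv was at 4.65 and Inhba at 4.06. With limma-voom the calls of Mefv, Inhba, Napsa and Clec4d were lost, with adjusted p from 0.0603 to 0.0998.

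**Figure D2:**
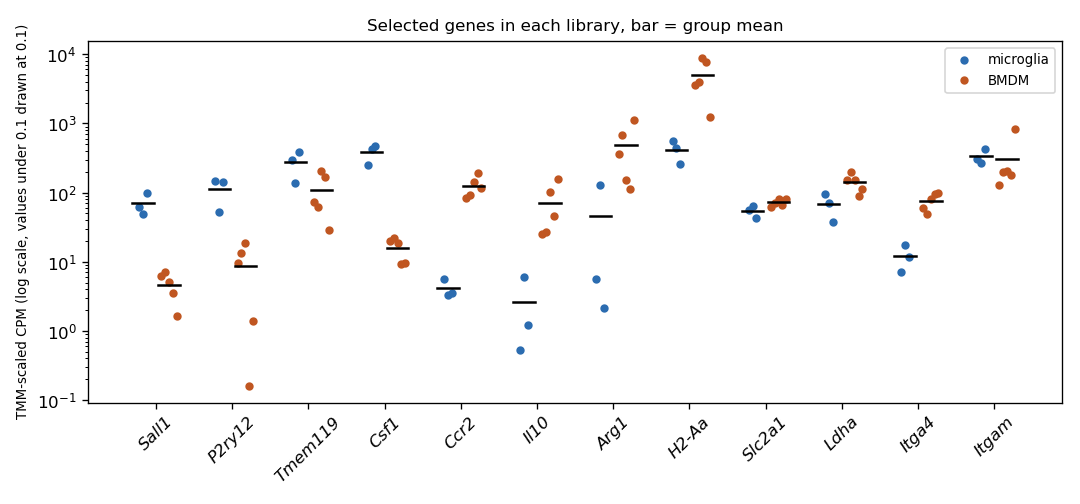
TMM-scaled CPM of 12 genes in each library on a log axis, with microglia in blue, BMDM in orange and black bars at the group means. Sall1 and Csf1 are higher in each of the 3 microglia libraries, and Ccr2 and Il10 in each of the 5 BMDM libraries.

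Among 26 measured immunosuppressive and alternative activation genes, 5 were higher in BMDM and 0 lower (6 higher when adjusted over the list alone). The camera adjusted p was 0.00081, and adjusted p = 0.11 with an estimated correlation; with only BMDM 1 to 3 the preset test gave 0.12. Il10 (chromosome 1, 131019845 to 131024974) rose by 4.79 (SE 0.90, adjusted p = 0.0134), from 2.60 ± 3.00 CPM (n = 3) to 70.7 ± 55.8 (n = 5). Microglia 2 held 6.03 CPM of Il10 against 0.526 and 1.22 in the other microglia, and without it the value was 6.32 (SE 0.94, adjusted p = 0.003). Il1rn, the interleukin 1 receptor antagonist, rose by 3.17 (SE 0.59, adjusted p = 0.0116). Both calls were lost without microglia 1 (adjusted p = 0.0732 for Il10 and 0.0672 for Il1rn) or without microglia 3 (0.157 and 0.0753), and that of Il10 also with limma-voom (0.0755). Arg1, which consumes arginine, was at 3.40 (SE 1.24, adjusted p = 0.221), with 130.5 CPM in microglia 2 against 5.57 and 2.11 in the other microglia. Without microglia 2 its value was 6.88 (SE 1.16, adjusted p = 0.0101). Cd274, which encodes PD-L1, was at 0.98 (SE 0.55, adjusted p = 0.49), and at 0.05 (SE 0.38, adjusted p = 0.942) with only BMDM 1 to 3. Of 23 inflammatory genes, 2 were higher and 0 lower (7 higher and 5 lower when adjusted over the list alone), with a camera adjusted p of 0.041 (0.23 with only BMDM 1 to 3) and adjusted p = 0.49 with an estimated correlation. Il1b rose by 2.61 (SE 0.51, adjusted p = 0.0167), a call lost without any 1 microglia library (adjusted p 0.0969 to 0.108), and Nos2 was at 3.83 (SE 1.21, adjusted p = 0.142). Microglia 2 held 2.01 CPM of Nos2 against 0.210 and 0 in the other microglia, and without it the value was 6.22 (SE 1.5, adjusted p = 0.0628).

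For glucose use, none of the 23 glycolysis and lactate transport genes was called in either direction (0 higher and 0 lower, also when adjusted over the list alone), while 20 had a positive fold. At an unadjusted p under 0.05 edgeR gave 6 higher and 1 lower, and DESeq2 called 2 higher. With only BMDM 1 to 3, edgeR called 4 higher, Pkm, Pfkp, Gapdh and Ldha, and 1 lower, Slc2a3 (-2.03, against -0.68 with all libraries). In that fit Pkm, a pyruvate kinase, was at 1.61 (SE 0.27, adjusted p = 0.00405). Genes named from that fit in this list, the PERK-ATF4 list and the lactylation list were chosen after their values were seen, apart from Ldha, Slc2a3 and Ep300. The median was 0.64, with a camera adjusted p of 0.00081, and adjusted p = 0.16 with an estimated correlation. The fry adjusted p was 0.058 for movement one way and 0.045 for change in either direction. Slc2a1 (chromosome 4, 119108711 to 119137983), the glucose transporter GLUT1, had 72.0 ± 8.49 CPM (n = 5) in BMDM and 54.4 ± 10.8 (n = 3) in microglia, a log2 fold change of 0.41 (SE 0.31, adjusted p = 0.674). Ldha, which makes lactate, was at 1.04 (SE 0.41, adjusted p = 0.249), and at 1.29 (SE 0.35, adjusted p = 0.0305) with only BMDM 1 to 3. Hk2 was at 0.26 (SE 0.41, adjusted p = 0.869), and the lactate exporter Slc16a3 at 0.62 (SE 0.53, adjusted p = 0.73) or -0.40 with only BMDM 1 to 3. In the hypoxia list 4 of 22 genes were higher and 0 lower (5 higher when adjusted over the list alone), with a camera adjusted p of 0.0026 and adjusted p = 0.16 with an estimated correlation. They were Ndrg1 (2.72, SE 0.53), Vegfa (2.69, SE 0.60), Hilpda (2.15, SE 0.49) and Bhlhe40 (1.75, SE 0.38), and each was lost without microglia 1 or microglia 2, with adjusted p from 0.074 to 0.22. Vegfa was at 1.92 with only BMDM 1 to 3. Without microglia 3 the calls of Vegfa, Hilpda and Bhlhe40 were lost as well (0.143, 0.181 and 0.19), as were those of Vegfa without BMDM 3 or BMDM 4 (0.0782 and 0.0699) and of Hilpda without BMDM 1, 2 or 3 (0.0697 to 0.0947). Hif1a was at -0.20 (SE 0.35, adjusted p = 0.895).

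No gene of the oxidative phosphorylation list was called among 38 measured (0 higher and 0 lower, also when adjusted over the list alone), with a median of 1.05, a camera adjusted p of 6.2e-08 and adjusted p = 0.35 with an estimated correlation. Its mean log2 CPM was 6.82 to 7.24 in BMDM 1 to 3, 6.12 in BMDM 4 and 5.14 in BMDM 5, and 5.22 to 6.01 in microglia. With only BMDM 1 to 3, 24 of the 38 were higher. Ribosomal protein genes, a set added after the data were seen, moved with the same libraries, as 45 of 91 were then higher and 1 lower. Their mean log2 CPM was 7.55 to 8.21 in BMDM 1 to 3, 6.87 in BMDM 4 and 5.93 in BMDM 5, and 6.292 to 6.997 in microglia. With all libraries, 15 oxidative phosphorylation genes were higher at an unadjusted p under 0.05, and DESeq2 called 6. The list of pyruvate entry and the tricarboxylic acid cycle had 0 of 24 genes called (2 lower when adjusted over the list alone) and a camera adjusted p of 0.86. Unadjusted, 3 were higher and 2 lower, DESeq2 called 1 each way, and with only BMDM 1 to 3 edgeR called 5 higher and 2 lower.

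Of the PERK-ATF4 stress response list, 0 of 21 genes were called (1 lower when adjusted over the list alone), with a median of -0.42 and a camera adjusted p of 0.068. Fry, which does not compare a list with other genes, gave an adjusted p of 0.0096 for movement downward and 0.0013 for change in either direction. In the fit of BMDM 1 to 3 alone, Psat1, Trib3 and Slc7a5 were lower (3 genes) and 0 were higher, with a median of -0.61. Unadjusted with all libraries, 1 was higher and 2 lower, and DESeq2 called 1 higher. Eif2ak3, which encodes PERK, was at -0.42 (SE 0.58, adjusted p = 0.852), and Atf4 at -0.37 (SE 0.42, adjusted p = 0.812). In the chaperone list 1 of 21 genes, Herpud1, was lower (also 1 when adjusted over the list alone), with a camera adjusted p of 0.041 and adjusted p = 0.35 with an estimated correlation. Herpud1 lost its call without microglia 3 (log2 fold change -1.32, adjusted p = 0.20) or without any 1 of BMDM 1 to 4 (0.0581 to 0.0702). None of 19 candidate lactylation enzymes was called (0 higher and 0 lower, also when adjusted over the list alone), and the camera adjusted p was 0.34. Fry gave an adjusted p of 0.0096 for movement downward and 0.019 for change in either direction, with a median of -0.19. With BMDM 1 to 3 alone, 1 was higher, Hdac8, and 4 were lower, Hdac1, Hdac2, Kat2b and Ep300, and the median was -0.54. Unadjusted with all libraries, 1 was higher and 2 lower, and DESeq2 called 0. Ep300, an acetyltransferase studied as a lactylation writer, was at -0.64 (SE 0.42, adjusted p = 0.584), and at -1.30 (SE 0.27, adjusted p = 0.0108) with only BMDM 1 to 3.

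In class II antigen presentation 4 of 10 genes were higher and 0 lower (7 higher when adjusted over the list alone), with a camera adjusted p of 3.2e-06 and adjusted p = 0.19 with an estimated correlation. H2-Aa rose by 3.60 (SE 0.68, adjusted p = 0.0124), lost without microglia 3 (adjusted p = 0.105) or microglia 2 (0.0643). The mean log2 CPM of the list was 7.35 to 8.45 in BMDM 1 to 4 and 5.14 in BMDM 5, against 6.02 to 6.17 in microglia. That mean counts each gene alike, and BMDM 5 lacked 2.86% of genes expected at 20 or more counts. In BMDM 5, H2-Aa was at 1222 CPM (259.5 to 561.1 in microglia) and H2-Ab1 at 1402 (389.3 to 511.7). H2-Eb1 was at 320.9 CPM there, within the 230.4 to 491.5 of microglia. No gene of the class I list (17 measured, camera adjusted p of 0.0089, adjusted p = 0.38 with an estimated correlation) or of the 29 interferon-stimulated genes (1.2e-05, and adjusted p = 0.35 with an estimated correlation) was called. Adjusted over the list alone, 3 class I genes were higher and 1 lower, and 4 interferon-stimulated genes were higher. Both lists stood highest in BMDM 3 and 4. The interferon list had a mean log2 CPM of 6.61 and 6.75 there, 5.43 to 5.87 in BMDM 1, 2 and 5, and 5.34 to 5.72 in microglia. The class I list had 7.39 and 7.45, against 6.39 to 6.68 in BMDM 1, 2 and 5 and 6.39 to 6.67 in microglia. DESeq2 called 3 class I and 5 interferon-stimulated genes higher, and at an unadjusted p under 0.05 edgeR gave 3 and 10. There were 3 class I and 8 interferon-stimulated genes higher with only BMDM 1 to 3, where the class I list had a camera adjusted p of 0.22 and a median of 0.29, against 0.58 with all libraries. For chemokine receptors, 4 of 12 were higher and 1 lower (the same counts when adjusted over the list alone), with a camera adjusted p of 0.00029 and adjusted p = 0.073 with an estimated correlation. Ccr1 rose by 2.92 (SE 0.48, adjusted p = 0.00527). Adhesion and matrix genes had 8 of 32 higher and 2 lower (13 and 5 when adjusted over the list alone), with a camera adjusted p of 3.5e-05 and adjusted p = 0.073 with an estimated correlation. Emilin2, a matrix glycoprotein, rose by 3.58 (SE 0.49, adjusted p = 0.00167).

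Among 26 macrophage transcription factors, Runx3 rose by 3.75 (SE 0.50, adjusted p = 0.00155), while Sall3 and Bhlhe41 fell by 2.94 (SE 0.42) and 2.33 (SE 0.36). In all 2 were higher and 3 lower (4 and 7 when adjusted over the list alone), and the camera adjusted p was 0.58. Of the immediate early and heat shock list, which responds to tissue dissociation, 2 of 30 genes were lower and 0 higher (6 lower and 1 higher when adjusted over the list alone), with a camera adjusted p of 0.0059 and adjusted p = 0.40 with an estimated correlation. These were Egr1 (-2.70, SE 0.42, adjusted p = 0.00354) and Egr3 (-3.55, SE 0.51, adjusted p = 0.00209). The cell cycle list had 0 of 39 genes called (also 0 when adjusted over the list alone), a median of -0.67 and a camera adjusted p of 0.0017, with adjusted p = 0.35 with an estimated correlation. Unadjusted, 1 was higher and 4 lower, DESeq2 called 0, and with only BMDM 1 to 3 edgeR called 2 lower. Mki67 was at -0.73 (SE 0.37, adjusted p = 0.425). The cell cycle list had a mean log2 CPM of 2.40 in BMDM 4 and 2.89 in BMDM 5. It had 3.31 to 4.23 in BMDM 1 to 3, and 4.05 to 4.25 in microglia. BMDM 4 and 5 lacked 4.99% and 2.86% of genes expected at 20 or more counts, so their low means can reflect lost transcripts. Mki67 was at 17.4 CPM in BMDM 4 and 57.4 in BMDM 5, against 51.3 to 65.9 in microglia. Disease-associated microglia genes had 3 of 24 lower and 0 higher (4 lower and 7 higher when adjusted over the list alone; camera adjusted p of 0.86). Complement had 2 of 14 higher and 1 lower (4 and 2 when adjusted over the list alone; 0.26). In these, C4b, a complement component, fell by 3.00 (SE 0.37, adjusted p = 0.000817), and Cd9 by 2.44 (SE 0.43, adjusted p = 0.00853). Iron handling had 2 of 14 higher and 0 lower (3 and 1 when adjusted over the list alone; 0.065), and cholesterol synthesis 0 of 22 (also 0 when adjusted over the list alone; 0.73), with 1 each way unadjusted, 1 each way with only BMDM 1 to 3 and 1 higher by DESeq2.

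Markers of other cells were measured beside these groups. The summed CPM of T and NK cell markers was 109.7 to 400.8 in BMDM and 24.3 to 51.4 in microglia, with 1 of 18 genes higher (10 when adjusted over the list alone; camera adjusted p of 3.2e-06, and adjusted p = 0.19 with an estimated correlation). Neutrophil markers summed to 184 to 380.2 CPM in BMDM and 43.9 to 72.3 in microglia, although both gates excluded Ly6G. Of 10 neutrophil markers 3 were higher (6 higher and 1 lower when adjusted over the list alone), with a camera adjusted p of 1.6e-05 and adjusted p = 0.073 with an estimated correlation. Trem1, which monocytes also express, rose by 3.80 (SE 0.59, adjusted p = 0.00354), or 4.77 without microglia 2. Across the BMDM libraries Trem1 held 73.8 to 193.7 CPM of the neutrophil sum, Il1r2 41.1 to 111.9 and S100a8 6.63 to 55.3. The lowest S100a8 was in BMDM 5, which had the highest sum. Border-associated macrophage markers summed to 509.7 to 1177 CPM in BMDM and 149.7 to 211.5 in microglia, with 3 of 12 higher and 1 lower (4 and 1 when adjusted over the list alone; camera adjusted p of 0.00021, and adjusted p = 0.073 with an estimated correlation). Among them, F13a1 and Ms4a7 are also in the monocyte-derived list. Astrocyte and glioma markers summed to 278.9 to 505.3 CPM in microglia and 81.2 to 243.8 in BMDM, with 1 of 16 lower (also 1 when adjusted over the list alone; camera adjusted p of 0.031, and adjusted p = 0.42 with an estimated correlation). Dendritic cell markers had 1 of 11 higher and 1 lower (the same when adjusted over the list alone; 0.041, or 0.075 with only BMDM 1 to 3, and adjusted p = 0.42 with an estimated correlation). Hemoglobin genes were lower in BMDM as a list (0 of 4 called, 1 lower when adjusted over the list alone; 0.0089, and adjusted p = 0.16 with an estimated correlation). The dendritic list had a median log2 fold change of 1.63, yet its summed CPM was 79.5 to 226 in BMDM and 174.6 to 376.1 in microglia. Fscn1, its 1 member called lower, held 133.7 to 315.5 CPM of that sum in microglia and 49.6 to 83.2 in BMDM. The other 10 measured members of the dendritic list had a positive fold. The hemoglobin list summed to 27.6 to 49.1 CPM in BMDM 1 to 4. In BMDM 5 it was at 161.3, within the 109.6 to 248.1 of microglia. Lists of B cells, oligodendrocytes, neurons and endothelial cells gave camera adjusted p values of 0.73, 0.90, 0.73 and 0.38.

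**Figure D3:**
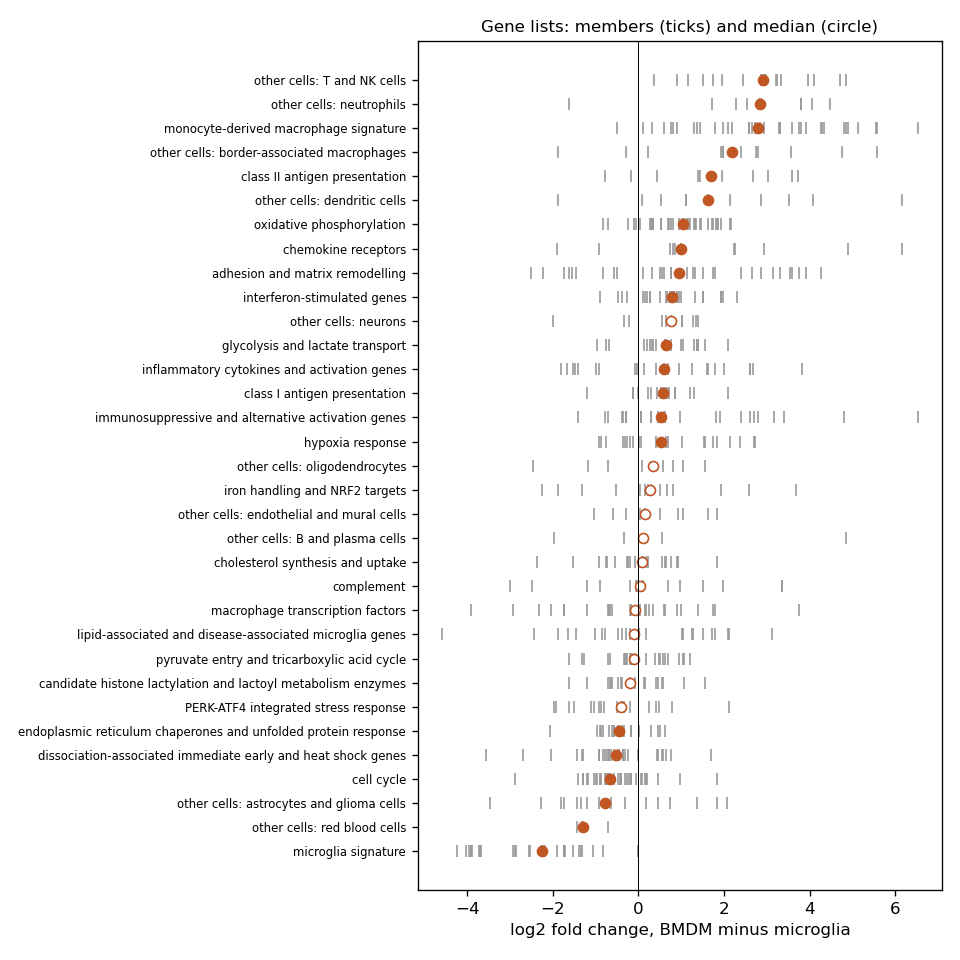
Log2 fold change of BMDM minus microglia for the members (ticks) and the median (circles) of 33 gene lists, with filled circles where camera with a preset correlation passed an adjusted p of 0.05. The monocyte-derived list has a median of 2.79 and the microglia list one of -2.25.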

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

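The tests of library complexity and of libraries that cut across the groups were chosen after the result was seen. Among 128 measures tested in the 5 BMDM libraries (library measures, list means and named genes), 11 had 1 library far from the other 4, where chance gives about 6.4. Of these, 7 were in BMDM 5 and 3 in BMDM 4.

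In BMDM 5, log2 CPM was 3.02 for Chil3 (5.18 to 5.86 in the others), 4.79 for Ccl7 (6.24 to 6.70), 2.89 for Cfp (5.05 to 5.93) and -1.04 for Lrrc3 (2.05 to 3.31). It was 7.07 for Nrg1 (3.53 to 4.06), 6.81 for Il1r2 (5.37 to 5.73) and 9.71 for Itgam (7.02 to 7.67). In BMDM 4, Slc1a3 was at -2.24 (3.35 to 3.93), the astrocyte and glioma list at 0.513 (2.42 to 3.05) and the cholesterol list at 1.73 (3.04 to 3.20). Slc1a3 had 0 CPM in BMDM 4, so -2.24 is only the value that the prior count of 2 gives. Lrrc3 had 0.276 CPM in BMDM 5, also near that limit. In BMDM 3, Cx3cr1 was at 9.89 (9.02 to 9.26).

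The first pattern weighed is that 2340 genes were called with only BMDM 1 to 3, against 317 with all 5. Fewer counts in BMDM 4 and 5 are argued against, as their counts without Gm42418 and mitochondrial rRNA lay near those of BMDM 1 to 3. They were 4151079 and 4528532, against 4437910 to 6008538. The ratio of calls was 7.38, and 7.20 after every library was thinned to one total, a step that could change little at such depths. Fewer libraries are argued against as well, because the other 9 pairs of BMDM libraries left out gave at most 693 calls. Of genes expected at 20 or more counts, 2.86% were absent in BMDM 5 and 4.99% in BMDM 4, against at most 0.111% in BMDM 1 to 3 and 2.76% in microglia 3, but the calls did not follow this order, with 273 when BMDM 4 alone was left out and 1138 without BMDM 5. Low complexity of both libraries and, as untested, a difference between mice stay open. Ddx3y, a Y-linked gene, was at 0.123 to 1.72 CPM in BMDM 1 to 3 and at 55.2 and 141 in BMDM 4 and 5. Gm42418 took 14.8% to 19.8% of counts in BMDM 1 to 3, 34.0% to 47.0% in microglia, and 41.2% and 48.9% in BMDM 4 and 5. Without BMDM 4 and 5, cell type and this difference in library composition therefore cannot be told apart.

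The second pattern is the higher oxidative phosphorylation list in BMDM; across all genes tested, log2 fold change and exon length had a Spearman correlation of -0.27. The median of 1.05 lay at percentile 99.9 of 10000 random lists matched on exon length and expression, which had a median of 0.459. Such lists do not keep the correlation of 0.52 among the genes of this one (adjusted p = 0.35 with an estimated correlation), so a bias for short and abundant transcripts stays open. Libraries that cut across the groups may account for it, because BMDM 4 and 5 together differed from microglia by -0.0445 in mean log2 CPM and BMDM 1 to 3 by 1.31. That joint value rests on BMDM 5, which at 5.14 lay below every microglia library (5.22 to 6.01). BMDM 4, at 6.12, lay above all of them. A difference between the cell types in BMDM 1 to 3 stays open.

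For the comparison as a whole, 1 of the 56 splits of the 8 libraries, the real one, gave as many as 317 called genes, and the highest other gave 134. This argues against a random grouping, though it is the smallest share that 56 splits can give. That other split set BMDM 1 to 3 against the rest, so differences between libraries apart from the labels also gave calls. The splits cannot tell such differences from cell type. For the gene lists, 1 of 56 splits gave 21 lists past the threshold, the real one, but the highest other gave 20. With BMDM 1 to 3 against microglia the 10 splits are too few for a share under 0.05; the real one (1 split) gave 2340 genes and the highest other 0.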

How the results depend on the processing

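All settings were chosen before the data were examined except the one without Gm42418 and mitochondrial rRNA genes. Against 183 genes higher and 134 lower in BMDM (317 with an absolute log2 fold change of at least 1), DESeq2 gave 601 and 313 (905), no filter 403 and 318 (721), and limma-voom with sample quality weights 1063 and 1668 (2404). Limma-voom without weights gave 250 lower. A test against a log2 fold of 1 gave 76 and 35. The cause was not tested for these, apart from the stricter hypothesis of the last. With only BMDM 1 to 3 against microglia, 1028 were higher and 1312 lower (2206). Of the 317 genes, 315 were also called by DESeq2, 244 by limma-voom and 309 without a filter. Leaving out 1 library gave 58 to 536 higher, 46 to 602 lower and 104 to 1127 with the larger fold. The lowest counts were without microglia 3 and the highest without BMDM 5, and leaving out microglia 1 or 2 also lowered the calls, to 118 and 164, with fewer libraries. RLE factors, library totals, the stricter filter and leaving out Gm42418 and mitochondrial rRNA kept each count within 1.5 times.

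Numbers 1 to 3 occur in both groups, but the labels do not say that a number marks the same mouse. The main fit therefore took no pairs, a choice made in advance. Same-numbered libraries had deviations correlated at 0.01, 0.27 and 0.32. Microglia 1 correlated best with BMDM 2 (0.12), and microglia 2 and 3 with their own number. The Y-linked gene Ddx3y was at 19.8 and 79.7 CPM in microglia 1 and 2 but at 0.133 and 0.123 in BMDM 1 and 2. This goes against a shared source for those numbers, and a block by number assumes pairs that the labels do not give. With the replicate block 1449 genes were higher and 1774 lower (2816), a fit in which BMDM 4 and 5 have no bearing on the difference.

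Of 33 lists, 21 passed with the preset correlation, 1 with an estimated correlation and 10 with fry, and 17 to 22 under the other settings. Of calls, 57.7% were higher, against 65.8% with DESeq2 and 36.1% with limma-voom. Library totals alone moved the log2 fold change of all genes by a median of 0.131, limma-voom by -0.19 and leaving out microglia 3 by -0.126.

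Among 71 called named genes, 33 stayed called with each library left out. Only 28 stayed called under every setting, the test against a log2 fold of 1 aside. A change of sign was seen for 0 of the 71, which says little, since they were picked for their calls in these same libraries. Of the named genes not called, 3 changed sign. Adgre1 was at -0.010 with limma-voom, -0.081 with weights, -0.102 with the block and -0.0030 with BMDM 1 to 3, and at -0.166 to 0.204 with 1 library left out. Itgam was at -0.915 to 0.094 with 1 library left out. Slc16a3, at 0.62 by edgeR with all libraries and no block, was at -0.118 with weights, -0.397 with the block and -0.402 with BMDM 1 to 3. At this depth and spread a log2 fold of 1 was rarely detectable.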

Other observations

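The Clec4 genes, a family of C-type lectins, were singled out after their values were seen, so their count is not a test of the family. The 7 members tested lie together on chromosome 6 between 122921848 and 123289870 (GRCm38), and 6 were higher in BMDM, while Clec4b1 was at 5.29 (SE 2.00, adjusted p = 0.228). Clec4e, a receptor for mycobacterial and dead-cell ligands, reached 104 ± 43.0 CPM (SD, n = 5) in BMDM and 4.17 ± 4.14 (n = 3) in microglia. Clec4n and Clec4a1 rose by 4.16 (SE 0.80) and 3.59 (SE 0.49) on the log2 scale, with adjusted p of 0.0159 and 0.00167 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Clec4a2 and Clec4a3 rose by 2.35 (SE 0.48) and 1.95 (SE 0.40). These genes resemble each other, so reads could have been shared among them, which was not tested; with library totals alone Clec4e was at 4.75, and without microglia 2 at 5.80.

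The glycolysis list, with no gene called by edgeR (6 higher and 1 lower at an unadjusted p under 0.05, and 2 higher by DESeq2), had a median of 0.64 at percentile 99.8 of random lists matched on exon length and expression. Random lists do not keep the correlation of 0.076 among its genes, and the list had adjusted p = 0.16 with an estimated correlation. Ribosomal protein genes, short and abundant as well, had a median of 0.70 at percentile 96.8, and of 1.06 with only BMDM 1 to 3, where 45 of 91 were higher and 1 lower by edgeR.

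Sex-linked transcripts differed between libraries of one group. Xist was at 367, 204 and 1806 CPM in microglia 1 to 3, at 510, 369 and 633 in BMDM 1 to 3, at 300.2 in BMDM 4 and at 7.05 in BMDM 5. The Y-linked gene Ddx3y was at 19.8, 79.7 and 0 CPM in microglia 1 to 3, at 0.133, 0.123 and 1.72 in BMDM 1 to 3, at 55.2 in BMDM 4 and at 141 in BMDM 5. Microglia 1, microglia 2 and BMDM 4 thus held Xist together with 19.8 CPM or more of Ddx3y. Ddx3y also set BMDM 4 and 5 apart from BMDM 1 to 3, so the sex of the source cannot be told apart from their other differences. The labels give no sex or pooling of mice.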
